A study of Mus musculus with 2 samples.

How the data were processed

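The samples are described as cultures of activated satellite cells, the muscle stem cells that lie on the fibre. They were grown as primary myoblasts from neonatal mouse hind limb and back muscle. Per the labels' protocols, muscle was digested with pronase, cells were enriched by differential sedimentation, and the cultures were grown on Matrigel in a serum-rich medium with bFGF. No sorting on surface markers is given in the sources used here. Pax7 was deleted by tamoxifen with a Pax7-driven, tamoxifen-inducible Cre and a floxed Pax7 allele: per the labels' protocols the dose was 75 µg per g of body weight, given from day 5 on 5 consecutive days. Whether the WT animals received tamoxifen is not given in the sources used here. The libraries were made from polyA-selected RNA.

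Per the file headers, the authors deposited expression as FPKM (fragments scaled to transcript length and to the size of the library), with 1 column for WT and 1 for Pax7 KO. The submitters' processing notes name TopHat2 2.0.9, Cufflinks 2.1.1, Cuffdiff 2.1.1 and the mm9 build, without saying what each was used for. The lowest value of either column was 0.001, which stood in 2031 rows of the WT column and 2590 rows of the KO column, and is treated here as "not detected". The authors also deposited a list of 713 genes higher and a list of 382 genes lower in KO, with a fold that is the ratio of the KO FPKM to the WT FPKM, per the file headers. The rule behind these lists is not given in the sources used here, and they hold no p-values. In the lower list, 21 symbols had a low line where the full table has a hyphen, and with that replaced the listed genes were all found in the table.

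There were 2 libraries and 1 library per genotype, so no spread between replicates exists, no significance test between the genotypes was run and no p-value is given. Expression was compared as log2((KO FPKM + 1) / (WT FPKM + 1)), called the log2 ratio below, in the 11751 genes whose mean of both libraries was an FPKM of 1 or more. The pseudocount of 1 understates the change of genes with low values. A gene was counted as higher or lower by 2-fold at a log2 ratio of 1 or more in size, so a gene of low FPKM can differ by 2-fold in FPKM and not be counted. Counts without the pseudocount, chosen after seeing the data, are given where they change a printed count of list members past 2-fold; folds given for single genes are ratios of the FPKM. The rows of the 1 symbol that occurs more than once were summed. The 2 columns were used as deposited. Because the median gene had a log2 ratio of 0.42, ratios are also given relative to the median gene, which means after subtracting 0.42; "as deposited" means without this subtraction. Without the pseudocount, the value subtracted was 0.50.

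For each of 28 gene lists, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A list was described as standing apart below the 2.5th or above the 97.5th percentile. Genes are not replicates, and the percentile describes these 2 libraries only. The lists, the rule for named genes, the thresholds and the alternatives were fixed before the data were examined. The rule named Pax7, the 15 genes with the largest and the 15 with the smallest log2 ratio (leaving out predicted genes, clones, ribosomal pseudogenes and small RNAs) and up to 4 members of each list with the largest change. Other genes were chosen after their values were seen: in the report they are Myog, Des, Ckm, Acta1, Acta2, Cdh5, Pecam1, Pcna, Ccnb1, Mki67, Id2, Id3, Igfbp5, Pparg, Cebpa, Prdm16, Itga7, Cxcr4, Cd34, Irf7, Cdon, Jsrp1, Tmem8c, Musk, Casq1, Tnni1, Mybpc2, Eln, Oasl1, S100a8, S100a9, Elane, Ltf, Gapdh, Fn1, Jun, Fos and Scx, and the rows that share a locus with a named gene. The genes that the closing section names from the second adipocyte, epidermal and granulocyte lists and from the imprinted list were also chosen after their values were seen. Some genes are not reported here.

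Sequencing depth was estimated from the values. In genes with few fragments the FPKM, multiplied by the right length, should fall on whole multiples of what 1 fragment is worth. The fit was loose: at the step chosen, the mean cosine of the values was 0.36 in WT and 0.36 in KO, and exact multiples would give 1. With the longest GENCODE M21 transcript as the length (98.0% of symbols matched), that step corresponded to about 25800000 fragments in WT and 21600000 in KO, if no scaling factor had been applied to a library. The worth of 1 fragment was thus 1.20 times larger in KO, a log2 difference of 0.26; the most frequent log2 ratio among 3135 genes with low values, which needs no gene length, was 0.27. Estimated fragments per gene from this step gave 95% exact (Clopper-Pearson) intervals for the log2 ratio without a pseudocount. These are approximate, assume that no scaling factor had been applied to a library, and cover counting error only, not variation between cultures or animals. In simulated data with this depth and 11631 genes, 12 of 11431 unchanged genes passed the 2-fold limit, while 16% of 50 genes simulated at 2-fold, 98% at 3-fold and 100% at 4-fold passed it. These simulated genes carried counting error only, with no shift of the whole table and no variation between cultures. The 12 genes are therefore no estimate of the wrong calls among the genes counted below. Of 200 lists of 25 genes drawn at random, 6% stood apart without a shift, and 91.5% did when shifted by 0.25. A rate near 6% without a shift follows from the limits at the 2.5th and 97.5th percentiles of random lists. Neither rate covers lists whose members vary together, so wrong calls among the gene lists below were not estimated.

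Coordinates are those of the deposited table, on mm9 per the submitters' processing notes. Among 17032 loci, the end minus the start equalled the RefSeq gene length in 6923 and fell 1 short of it in 436, so the starts were read as counted from 0, and 1 was added. The GRCm38 annotation was used for gene lengths and older symbols only. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were pseudocounts of 0.1 and 0.5, centring on the median gene, upper-quartile scaling, no filter or a mean FPKM of 5, a 1.5-fold limit, the highest row of a repeated symbol, the authors' lists, unmatched random lists, and lists without shared members.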

Results

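The series asked which genes depend on Pax7, the paired-box transcription factor of satellite cells, in muscle progenitors of young mice. It holds 1 polyA RNA-seq library of cultured progenitors from wild-type neonates (WT) and 1 from neonates in which Pax7 had been deleted (Pax7 KO). With 1 library per genotype, every difference is one between these 2 libraries and has no replicate check. The table listed 23236 rows, of which 11751 genes had a mean FPKM of 1 or more. Depth was about 25800000 fragments in WT and 21600000 in KO, as estimated from the values on the assumption that no scaling factor had been applied to a library. Across these genes, which are not independent replicates, log2(FPKM + 1) correlated between the libraries with r = 0.96.

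Pax7 itself (chromosome 4, 139293996 to 139388883, mm9) was the first check of the labels. It stood at 3.21 FPKM in WT and 0.769 FPKM in KO, 4.17-fold lower. The values rested on about 485 and 97 fragments, and the log2 ratio without a pseudocount was -2.06, with a 95% exact counting interval of -2.39 to -1.74. The direction goes with the genotype label. Other genes of satellite cells, which were not targeted, were lower as well, Cdh15 by 2.85-fold and Myf5 by 9.34-fold. The direction of Pax7 alone therefore does not show the deletion. The deposited value covers the whole gene, so it does not show whether the remaining fragments came from the part of the gene that was deleted.

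Most genes had higher deposited values in KO. The median gene had a log2 ratio of 0.42 with the pseudocount, and its FPKM was 1.42-fold higher in KO. The housekeeping gene Gapdh, a glycolytic enzyme, was at 1308 FPKM in WT and 1537 FPKM in KO, a log2 ratio of 0.23 as deposited and of -0.19 relative to the median gene. As deposited, 595 genes were at least 2-fold higher and 81 at least 2-fold lower, so that 88.0% of them were higher. Of the 81 lower rows, 41 were small RNA rows, as were 63 of the higher rows. In counts chosen after seeing the data, 513 were higher and 37 lower without small RNA rows and genes under 500 nt, 469 higher and 40 lower without genes that share a locus, and 1204 higher and 118 lower without a pseudocount. With a mean FPKM of 5 or more, 408 were higher and 32 lower. After centring on the median gene, 159 were higher and 170 lower, so that 48.3% were higher, and with upper-quartile scaling 153 were higher and 144 lower (51.5% higher). The authors' deposited table of called genes holds 713 higher and 382 lower genes. Of the 81 lower genes as deposited, 81 were in the authors' lower list, and 501 of the 595 higher genes were in their higher list. Those lists rest on the same 2 libraries, so the overlap is no independent check. The direction of any gene with a log2 ratio between 0 and 0.42 depends on this scaling, and values are therefore given relative to the median gene where that matters.

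**Figure D1:**
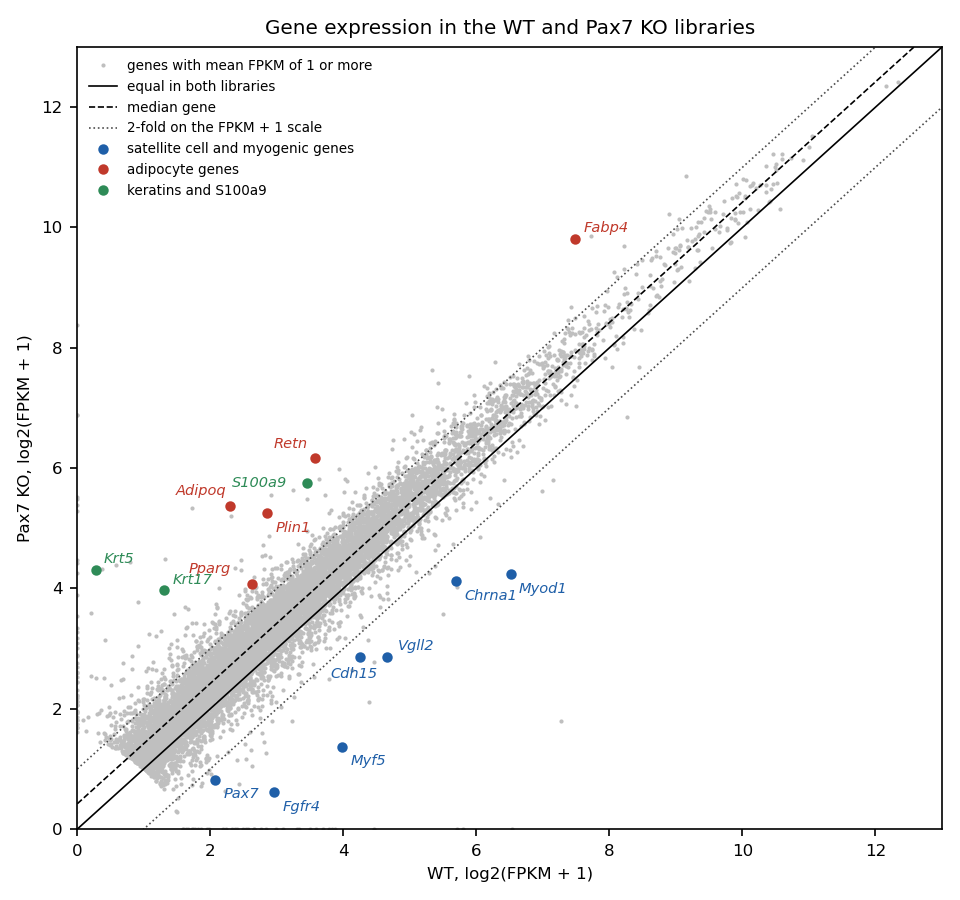
Expression of the 11751 genes with a mean FPKM of 1 or more, as log2(FPKM + 1) in WT (x axis) and Pax7 KO (y axis), 1 point per gene and 1 library per axis. The dashed line of the median gene lies 0.42 above the solid line of equal values, and the dotted lines mark a 2-fold difference; Myf5, Fgfr4 and Myod1 lie below the lower dotted line, Krt5 and Adipoq above the upper.

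Myf5, Fgfr4, Myod1 and Cdh15, genes of satellite cells and myoblasts, were lower in KO. Myf5 (chromosome 10, 106919964 to 106923190), a myogenic determination factor, was at 14.8 FPKM in WT and 1.58 FPKM in KO, 9.34-fold lower. Fgfr4 (chromosome 13, 55254179 to 55270120), an FGF receptor of myoblasts, was at 6.76 FPKM in WT and 0.526 FPKM in KO, 12.9-fold lower. Myod1 (chromosome 7, 53631844 to 53634462), the other early determination factor, was at 90.4 and 17.9 FPKM, 5.04-fold lower. Cdh15, which encodes M-cadherin of satellite cells, was at 17.9 FPKM in WT and 6.29 FPKM in KO. The counting intervals of the log2 ratio without a pseudocount were -3.60 to -2.87 for Myf5 and -2.45 to -2.22 for Myod1. In the same comparison, adipocyte and endothelial markers had median log2 ratios of 1.82 and 0.77.

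Of the 19 muscle stem cell markers above the expression limit, 4 were at least 2-fold lower (Myf5, Fgfr4, Cdh15 and Pax7), 2 were at least 2-fold higher and 13 were within 2-fold. Relative to the median gene, 5 were at least 2-fold lower and none higher; without the pseudocount these were 7 and none. The list's median log2 ratio was -0.21, below those of all 10000 matched random lists. The 2 higher members were Cxcr4, a chemokine receptor, at 56.3 FPKM in WT and 135 FPKM in KO, and Cd34, a surface sialomucin, at 30.0 and 61.7 FPKM. Both are also expressed by endothelial cells, whose markers had a median log2 ratio of 0.77. The row of Cd34 shares its locus with a predicted gene of much lower FPKM. Relative to the median gene, Cxcr4 and Cd34 were higher by 0.82 and 0.59, short of 2-fold. Itga7, a laminin receptor subunit of muscle cells, was at 43.6 FPKM in WT and 34.1 FPKM in KO.

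Of 21 myogenic regulators and fusion genes, 4 were at least 2-fold lower, 1 was at least 2-fold higher (Igfbp5, an IGF binding protein, at 1.00, or 0.58 relative to the median gene) and 16 were within 2-fold, with a median log2 ratio of -0.16, again below all random lists. Relative to the median gene, 6 were at least 2-fold lower, with Cdon and Jsrp1 added, and none higher; without the pseudocount these were 9, with Myog, Tmem8c and Musk added, and none. As deposited, the lower ones besides Myod1 were Chrna1 and Chrnd, subunits of the muscle acetylcholine receptor, and Rbm24, a muscle splicing regulator. Their log2 ratios were -1.57, -1.29 and -1.26. Myogenin (Myog), the factor of terminal differentiation, was low in both libraries, at 2.56 FPKM in WT and 1.44 FPKM in KO. Desmin (Des), the muscle intermediate filament, was at 75.8 and 67.6 FPKM. Of 29 sarcomere and excitation-contraction genes, none passed a log2 ratio of 1 in size; without the pseudocount 1 did, Pygm, muscle glycogen phosphorylase, which was 2.04-fold higher in FPKM. Their median was 0.17, or -0.25 relative to the median gene, at percentile 0.34. Ckm, muscle creatine kinase, was at 9.33 and 9.50 FPKM, and Acta1, skeletal actin, at 37.3 and 43.5 FPKM. The 2 members that were more than 2-fold lower relative to the median gene were Eno3, muscle enolase, at -1.19, and Actn2, sarcomeric alpha-actinin, at -1.16; without the pseudocount there were 5, with Casq1, Tnni1 and Mybpc2 added.

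Further genes were named because they were among the 15 with the lowest ratios. Vgll2, a muscle-enriched cofactor of TEAD factors, was at 24.3 FPKM in WT and 6.29 FPKM in KO. Pitx3, a homeobox factor, was at 4.39 and 0.688 FPKM, and summed with Elovl3, which shares its locus, had a log2 ratio of -1.41. Gal, the neuropeptide galanin, was at 51.1 and 15.3 FPKM. St8sia2, a polysialyltransferase, had a log2 ratio of -1.59, and Glycam1, a mucin-like adhesion molecule, of -2.27. Xkrx was at 306 FPKM in WT and 114 FPKM in KO. The 3 lowest ratios of the 15 belonged to rows that share a locus with an overlapping or near-identical row. Rps27, a ribosomal protein gene, was at 154 FPKM in WT and 2.48 FPKM in KO, but summed with Gm9846 at the same locus it was 647 and 946 FPKM, a log2 ratio of 0.55. Atp6v0c-ps2 and Prl2c4 were likewise near or at the lowest listed value in KO, while their sums with Atp6v0c and Prl2c3 had log2 ratios of 0.55 and 0.69. These 3 rows are therefore uncertain.

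Adipocyte genes were higher in KO. Adipoq (chromosome 16, 23146609 to 23158041), which encodes the adipocyte hormone adiponectin, was at 3.91 FPKM in WT and 40.4 FPKM in KO, 10.3-fold higher. Fabp4 (chromosome 3, 10204343 to 10208576), a fatty acid carrier of adipocytes, was at 179 and 899 FPKM, 5.03-fold higher. Retn, which encodes the hormone resistin, Cidec and Plin1, which encode lipid droplet proteins, had log2 ratios of 2.60, 2.41 and 2.40. Gpd1, glycerol-3-phosphate dehydrogenase, and Car3, a carbonic anhydrase abundant in fat, had log2 ratios of 2.38 and 2.64. Of 11 adipocyte and brown fat markers above the expression limit, 10 were at least 2-fold higher and none lower, and 9 remained at least 2-fold higher relative to the median gene. The median log2 ratio of 1.82 exceeded all 10000 random lists. Pparg and Cebpa, the transcription factors of adipocyte differentiation, were 3.09-fold and 2.82-fold higher. The member within 2-fold was Prdm16, a brown fat regulator, with a log2 ratio of 0.41. The 10 higher members were also in the higher list of the authors' deposited table, which rests on the same 2 libraries.

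Epidermal keratins had the 3 largest ratios of the named genes. Krt5 (chromosome 15, 101537501 to 101543322) was at 0.212 FPKM in WT and 18.9 FPKM in KO, with a counting interval of 5.67 to 7.44 on the log2 scale. Krt14, its partner in basal keratinocytes, was at 0.496 and 19.9 FPKM. Krt17 and Krt6a had log2 ratios of 2.66 and 3.38; Krt6a shares a locus with 10 other rows, of which Krt6b had a ratio of 1.63. Aldh1a1, a retinaldehyde dehydrogenase, was at 0.340 and 7.79 FPKM. Of 3 myeloid genes chosen after their values were seen, S100a8 was 4.43-fold, S100a9 5.29-fold and Elane, neutrophil elastase, 7.62-fold higher, whereas Ltf, the granule protein lactoferrin, was at 9.19 FPKM in WT and 8.66 FPKM in KO. Ndufs5, a complex I subunit, had a log2 ratio of 3.17, but shares its locus with BC002163, the sum with which had a ratio of 2.27. Apoo-ps, a pseudogene, was at the lowest listed value in WT, while the sum with Apoo had a log2 ratio of 0.10. Both rows are uncertain.

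Endothelial and smooth muscle genes were abundant in both libraries, so a difference between the libraries need not be one within satellite cells. In WT the endothelial junction genes Cdh5 and Pecam1 stood at 103 and 107 FPKM, and smooth muscle actin (Acta2) at 626 FPKM; in KO the values were 170, 185 and 642 FPKM. Of 14 endothelial markers, 4 were at least 2-fold higher and none lower, and the median of 0.77 lay at percentile 99.4. Cldn5, an endothelial tight junction gene, had the largest ratio of them, 1.85. Relative to the median gene, Cldn5 was the 1 marker at least 2-fold higher. The lists of mesenchymal cell types did not stand apart with the settings used here: fibroblast and fibro-adipogenic progenitor markers had a median of 0.60 (percentile 95.7, 14 genes), smooth muscle and pericyte markers 0.39 (percentile 16.3, 14 genes) and tendon and cartilage markers 0.37 (percentile 31.7, 9 genes). The fibroblast list passed the upper limit with pseudocounts of 0.1 and 0.5 (percentiles 99.9 and 99.1), with upper-quartile scaling (99.5) and with a mean FPKM of 5 or more (99.7), and the last also moved the tendon and cartilage list to 99.97. Within these, Kcnj8, a potassium channel of pericytes, was 4.66-fold higher. The cartilage genes Col2a1 and Acan were 4.06-fold and 3.81-fold higher, while Scx, a tendon transcription factor whose locus is shared with 2 other rows, had a ratio of -0.87. Schwann and glial markers had a median of 0.50 (percentile 72.8, 11 genes) and macrophage and leukocyte markers 0.19 (percentile 12.3, 11 genes). The latter were at low values, and summed to 33.5 FPKM in WT and 40.8 FPKM in KO. Erythroid markers rested on 3 genes, with a median of 1.83 (percentile 100). Hba-a1 had a ratio of 1.83 and shares its locus with the near-identical Hba-a2, while Hbb-b1 and Hbb-b2 share another locus and went in opposite directions. These rows are therefore uncertain singly. Summed by locus, the beta-globin rows were at 3.22 FPKM in WT and 12.7 FPKM in KO, a log2 ratio of 1.70, and Hba-a1 with Hba-a2 had a ratio of 1.83; relative to the median gene the sums were at 1.28 and 1.41. Without a filter on low values the list lay at percentile 15.9, inside the limits.

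Cell cycle genes lay below the median gene, while their deposited values differed little between the libraries. Adipocyte and endothelial markers, which stood apart upwards, had medians of 1.82 and 0.77. Of 36 mitosis genes, 36 lay below the median gene and none differed by 2-fold; the median log2 ratio was -0.12, or -0.54 relative to the median gene, below all 10000 random lists. Plk1 and Aurkb, mitotic kinases, had ratios of -0.45 and -0.36. The cyclin gene Ccnb1 was at 34.9 FPKM in WT and 31.2 FPKM in KO, and the proliferation marker Mki67 at 11.6 and 9.76 FPKM. Of 36 DNA replication genes, 35 lay below the median gene, with a median of -0.04, also below all random lists. Rrm2, a subunit of ribonucleotide reductase, had a ratio of -0.92 and Cdc6, a replication licensing factor, -0.70. Pcna, the replication clamp, had a ratio of 0.30 as deposited and of -0.12 relative to the median gene, so its direction flips with the scaling. Genes of CDK inhibitors and p53 targets had a median of 0.46, at percentile 66.0, and did not stand apart. Among them Phlda3, a p53 target, and Btg2, an antiproliferative gene, had ratios of 1.11 each, and were short of 2-fold relative to the median gene. Without the pseudocount, 6 members were at least 2-fold higher as deposited and none relative to the median gene.

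**Figure D2:**
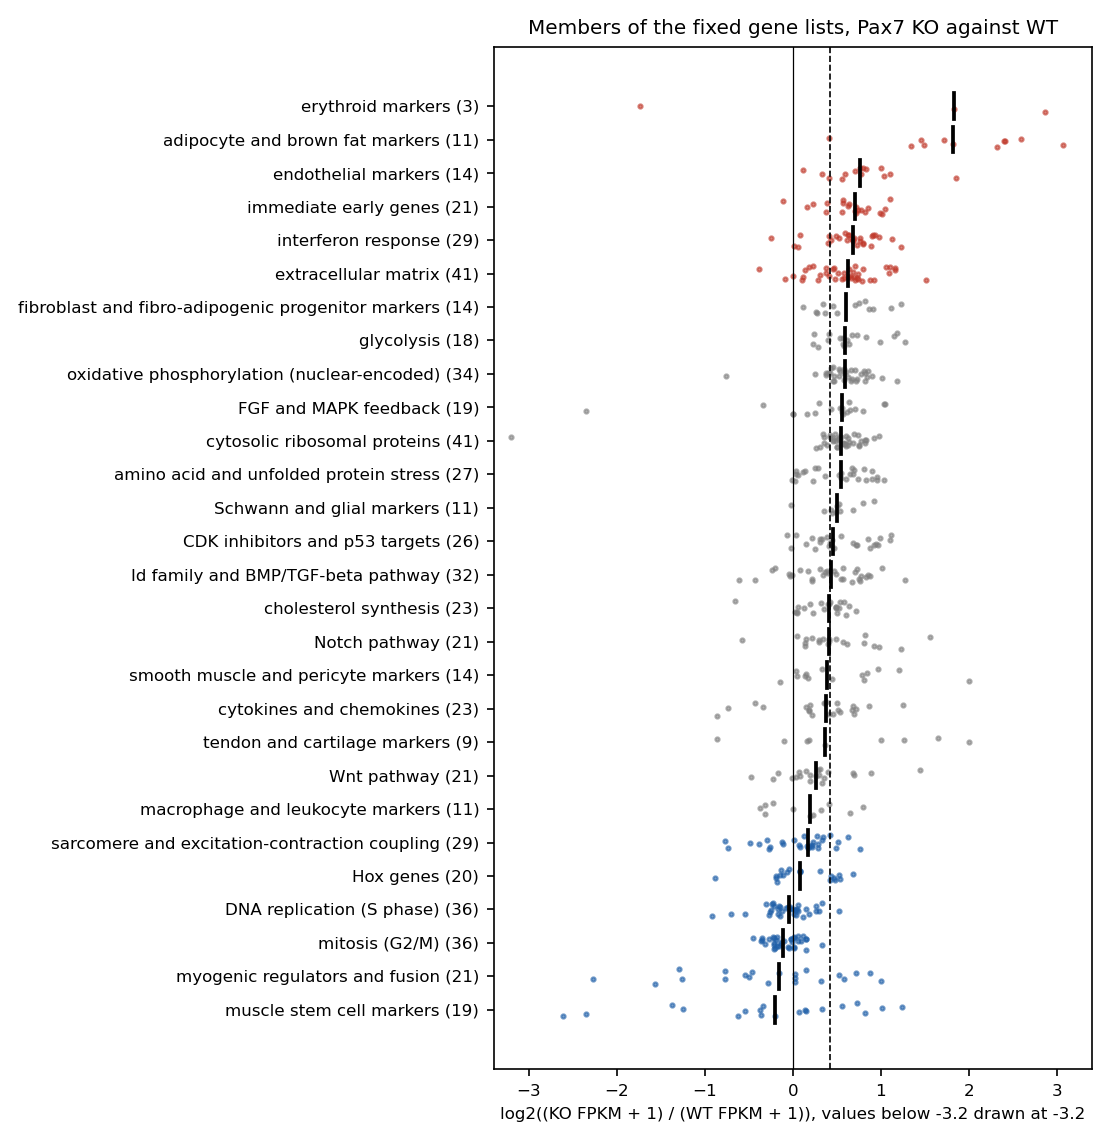
Log2 ratio (x axis, KO over WT with a pseudocount of 1) of each member of the 28 gene lists, 1 point per gene, with the number of genes in brackets and black bars at the medians; the dashed line is the median gene at 0.42, and the ribosomal gene Rps27, at -5.47, is drawn at the left end of the axis. Lists whose median stands apart above matched random lists are red, those below blue and the others grey; the medians of erythroid and adipocyte markers, 1.83 and 1.82, are the highest and that of muscle stem cell markers, -0.21, the lowest.

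The lists of extracellular matrix, interferon response and immediate early genes stood apart upwards. Extracellular matrix genes had a median of 0.63 (percentile 98.9, 41 genes), with 6 at least 2-fold higher and none lower, and 7 without the pseudocount, which added Eln, elastin. Relative to the median gene 1 of the 6 remained, Col11a1, a collagen of cartilage. In the same comparison the cartilage genes Col2a1 and Acan were 4.06-fold and 3.81-fold higher, within a list at percentile 31.7, and the fibroblast list lay at percentile 95.7, and at 99.1 to 99.9 under the 4 alternatives given with it. The adipocyte and endothelial lists stood apart upwards beside this list and the 2 that follow, with medians of 1.82 and 0.77. Col6a1, Col6a2 and Col6a3, the collagen VI chains, had ratios of 1.16, 1.16 and 1.10, Fn1, fibronectin, 1.06 and Col11a1 1.52. Interferon response genes had a median of 0.68 (percentile 99.99, 29 genes), with 2 at least 2-fold higher, Rsad2 and Cxcl10, and 11 without the pseudocount. Irf7, an interferon regulatory factor, was at 6.53 FPKM in WT and 5.34 FPKM in KO. With a mean FPKM of 5 or more the list held 12 genes and lay at percentile 96.2, inside the limits. Immediate early genes had a median of 0.71 (percentile 99.3, 21 genes). Its 3 members at least 2-fold higher were Btg2, Fosb and Dusp1, with ratios of 1.11, 1.05 and 1.02, to which leaving out the pseudocount added Atf3, while Jun and Fos had ratios of 0.71 and 0.74. Relative to the median gene, none of the interferon or immediate early genes was 2-fold higher with the pseudocount, and Rsad2, Usp18 and Oasl1 were without it. Hox genes stood apart downwards, with a median of 0.08 (percentile 0.36, 20 genes); with a mean FPKM of 5 or more, 2 genes were left and the list did not stand apart (percentile 27.7). Hoxc11 was at 3.30 FPKM in WT and 1.33 FPKM in KO. The other Hox genes named by the rule went the other way. Hoxd9, Hoxb9 and Hoxa5, the last with a shared locus, were 2.04-fold, 1.79-fold and 1.67-fold higher as deposited. Of the 20 members, 7 lay above the median gene and 13 below it.

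The remaining lists did not stand apart. Notch pathway genes had a median of 0.41 (percentile 29.5), with Dll4, a Notch ligand, at 1.56 and Nrarp, a Notch feedback gene, at 1.22. Dll4 and Nrarp were at 1.14 and 0.80 relative to the median gene, and 12 of the 21 members lay below it. FGF and MAPK feedback genes had a median of 0.56 (percentile 91.3), with Dusp4 and Dusp6, MAPK phosphatases, at 1.05 and 1.04. Relative to the median gene these were 0.63 and 0.62. The largest change in this list was that of Fgfr4, at -2.35. The Id family and BMP/TGF-beta list had a median of 0.43 (percentile 45.8), and its Id genes, which encode inhibitors of bHLH factors, differed in direction: Id1 had a ratio of 1.01, Id3 of 0.49 and Id2 of -0.62, which relative to the median gene were 0.59, 0.07 and -1.04. Wnt pathway genes had a median of 0.27 (percentile 9.12), and 17 of the 21 members lay below the median gene. Wnt4 went the other way, at 1.45, from a low WT value of 0.399 FPKM. Cytokines and chemokines had a median of 0.38 (percentile 15.6), with Saa3, an acute phase gene, at 1.25 and Cxcl5 at -0.86. Glycolysis genes had a median of 0.60 (percentile 90.01), with Bnip3 and Slc16a3 at 1.27 and 1.18. Nuclear-encoded oxidative phosphorylation genes had a median of 0.59 (percentile 89.8), cholesterol synthesis genes 0.41 (percentile 21.4), amino acid and unfolded protein stress genes 0.54 (percentile 75.5) and cytosolic ribosomal protein genes 0.55 (percentile 77.0). Of the 28 lists, 6 stood apart upwards, 6 downwards and 16 did not.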

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

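There was no replicate to leave out. No paired analysis was possible because each genotype had 1 library. Counts of higher and lower genes depended on scaling, pseudocount and threshold. The 595 higher genes became 159 when ratios were centred on the median gene, 153 with upper-quartile scaling, 1104 with a pseudocount of 0.1 and 3521 at 1.5-fold. The 81 lower genes became 170 when centred, 144 with upper-quartile scaling, 168 at 1.5-fold, 32 with a mean FPKM of 5 or more and 382 in the authors' deposited table. In alternatives chosen after seeing the data, 37 lower genes were left without small RNA rows and genes under 500 nt, 40 without genes that share a locus, and the higher genes numbered 97 when the first of these was combined with centring and 1204 without a pseudocount. The log2 ratio of Pax7 was -1.25, and was -1.93 and -1.55 with pseudocounts of 0.1 and 0.5, -1.67 when centred and -1.45 with upper-quartile scaling, negative in each. For the position of the 28 lists, centring is no test, because subtracting 1 constant cannot change a percentile, nor is keeping the highest row of the repeated symbol, which is not among the genes compared. Leaving out shared members removed none from 21 lists. Of the 175 other list values under alternatives, 163 kept their call and none reversed, and the muscle stem cell, myogenic, sarcomere, DNA replication, mitosis, matrix, immediate early, endothelial and adipocyte lists stayed on their side of the limits in each of these. With a mean FPKM of 5 or more, the interferon list lay at percentile 96.2 and the Hox list, with 2 genes left, at 27.7. The fibroblast list passed the upper limit with a pseudocount of 0.1 (99.9), of 0.5 (99.1), with upper-quartile scaling (99.5) and with a mean FPKM of 5 or more (99.7), the last of which also moved tendon and cartilage markers to 99.97. A pseudocount of 0.1 moved CDK inhibitors and p53 targets to 98.6. Unmatched random lists moved oxidative phosphorylation to 99.4 and ribosomal proteins to 98.3. Without a filter, macrophage markers moved to 0.26 and erythroid markers to 15.9. Apart from changes that follow from which genes remain, the cause was not tested. Counting error limits genes of few fragments: in C1qb, with about 60 and 33 fragments, the interval of the log2 ratio, -1.26 to 0.04, includes 0.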

Other observations

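The second adipocyte, epidermal and granulocyte lists were tests set before their own values were seen, though after Adipoq, the keratins, S100a8, S100a9 and Elane had been; the other tests below, and the imprinted gene list, were chosen after the results were seen. Of 19 genes of fat storage outside the first adipocyte list, 9 were at least 2-fold higher as deposited and 5 relative to the median gene (10 and 6 without the pseudocount, which adds Slc7a10), and none was lower by any of these. Their median log2 ratio was 0.96 as deposited and 0.53 relative to the median gene. Scd1, a fatty acid desaturase, and Dgat2, which makes triglyceride, were 3.07-fold and 3.63-fold higher, and Pnpla2, a triglyceride lipase, 2.55-fold. Relative to the median gene, the fatty acid synthesis enzymes Fasn, Acaca and Elovl6 were at -0.11, -0.08 and -0.33, Acly was at 0.11 and Me1 at 0.62. Other members lay as close to the median gene, such as Pnpla3 at -0.01 and Slc2a4 at 0.11. Of 11 granulocyte genes, 6 were at least 2-fold higher as deposited and 1, Camp, relative to the median gene (7 without the pseudocount, and 4 relative to the median gene, Camp, Prtn3, Ctsg and Chi3l3), with a median of 0.67 relative to it. Granule genes went both ways relative to the median gene: Camp, Ngp, Mpo and Prtn3 were 4.31-fold, 2.73-fold, 2.73-fold and 3.56-fold higher as deposited, whereas Ltf and Mmp9 were at 0.942-fold and 1.05-fold of their WT values. The receptors Cxcr2 and Csf3r were at 0.96-fold and 0.95-fold. Of 14 epidermal genes, 2 were at least 2-fold higher as deposited with the pseudocount, Jup and Dmkn, and 1, Dmkn, relative to the median gene. Without the pseudocount 7 were, as Lamb3, Pkp1, Ppl, Lgals7 and Sfn were 2.06-fold, 2.35-fold, 2.67-fold, 3.08-fold and 2.15-fold higher in FPKM, and relative to the median gene 2, Dmkn and Lgals7. The median was 0.29 relative to the median gene, and Cdh1 and Klf5 were at 0.864-fold and 0.781-fold of WT in FPKM. The most abundant members were Scd1 at 41.6 FPKM in WT and 128 in KO, the epidermal list's Itga6, also an endothelial gene, at 19.6 and 34.5, and the granulocyte list's Cxcr2 at 19.3 and 18.5. None of the genes of these lists is in the lists fixed earlier.

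Among 22 imprinted genes, of which Igf2, Cdkn1c and Dcn are also in the lists above, the median log2 ratio of 0.56 lay at percentile 93.8, inside the limits. Peg10 was the lowest of them, at 0.503-fold of its WT value, and Plagl1, a zinc finger factor, was at 0.673-fold. The growth factor gene Igf2 and H19 of the same cluster were at 0.45 and -0.13 relative to the median gene.

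The first pattern is the shift of the whole table, by a median log2 ratio of 0.50 without a pseudocount. The values argue against a bias with gene length as its whole cause, because the median ratio was still 0.41 in the longest 10% of genes, against 0.64 in the shortest. The summed FPKM times length came to 61.9% of all fragments in WT and 84.9% in KO, a log2 ratio of 0.46. This value is fixed by how FPKM is built, so a larger share of KO fragments in listed genes and a scaling factor applied to a library cannot be told apart. The share held by unlisted transcripts would need the reads.

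The second pattern is the lower level of Myf5, Myod1, Fgfr4 and Cdh15, whose median was -2.73 relative to the median gene. If the KO culture merely held fewer muscle cells, every gene expressed by muscle cells alone would be lower by the same factor. The lowest of 29 sarcomere genes lay at -1.19 relative to the median gene, above that median. On this scale the sarcomere genes thus did not share the fall of Myf5, Myod1, Fgfr4 and Cdh15. Those genes were named for the size of their change, and the pseudocount limits how far a gene of low FPKM can fall. Whether other cells expressed sarcomere genes was not tested. The comparison therefore cannot decide whether fewer muscle cells were the whole cause. More differentiation among fewer cells may still offset a loss in the sarcomere genes, and this was not tested. With 1 library per genotype, an effect of Pax7 loss and a difference between the 2 cultures cannot be told apart. Nor can an effect of tamoxifen or of the Cre, because whether the WT animals received or carried these is not given.

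The third pattern is the higher level of adipocyte, keratin and some granulocyte genes. A lower share of muscle cells alone would raise the markers of every other cell type alike, but the lower quartile of the adipocyte list exceeded the upper quartile of the smooth muscle and pericyte list by 0.65. The lists thus did not rise alike, but they were set against each other after the results were seen. The comparison cannot exclude a lower share of muscle cells as part of the cause. More adipocytes or adipocyte-like cells, more epidermal cells and more granulocytes in the KO culture were each tested with a second list. Each list lay above all random lists (percentile 100). The cell types were picked because other genes of theirs were high in these same 2 libraries, so the percentiles cannot decide. Each remains a candidate explanation. Only 14 of 30 epidermal and 11 of 20 granulocyte genes passed the expression limit. Some had a WT FPKM below 1, such as Dmkn at 0.059 and Chi3l3 at 0.486, and passed the limit only through their KO value. Such members can raise a list's median, and percentiles of the second lists without the limit were not computed. The granulocyte genes Cxcr2, Csf3r, Ltf and Mmp9 stayed near their WT values, and macrophage and leukocyte markers lay at percentile 12.3. Cells were enriched by differential sedimentation, and no cell sort is given in the sources used here. Whether cells carried over from dissection or a change of fate after Pax7 deletion brought these transcripts was not tested. An effect of tamoxifen, of the Cre or of the culture cannot be told apart from these.

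Small RNA rows, which polyA libraries of fragments measure poorly, were over-represented among extreme ratios: 70.3% of 148 such rows passed 2-fold, against 4.93% of the other rows. In the authors' deposited table the lower list reached up to a fold of 0.70, and 185 of its 382 genes were less than 2-fold lower, while the higher list began at 1.95. Divided by the fold of the median gene, those limits were 0.494 and 1.38.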
